A study of Mus musculus with 30 samples.

How the data were processed

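The series holds 30 arrays of phagocytes sorted from the Peyer's patches of C57BL/6 female mice, each replicate a pool of 42 mice. Per the labels' protocols, patches were digested with collagenase, CD11c+ cells were enriched with beads and sorted by flow cytometry, and 2 to 20 ng of total RNA was amplified and hybridised to Affymetrix Mouse Gene 1.0 ST arrays. LysoDC were gated as CD11c high, MHC class II high, SIRPa+, BST2+ and CD4-, and LysoMac as CD11c high, MHC class II low and CD4+. Per the submitters' processing notes, the authors processed the arrays with Expression Console 1.4.1 and RMA, and the deposited values are log2 levels. The genome build, the sort days and whether all arrays were normalized in 1 run are not given in the sources used here. 

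Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. A gene was tested by its brightest probe set among those with 1 symbol. A gene or probe set was kept where at least 3 arrays of the block lay at or above a filter level, the median over the block's arrays of probe sets with 1 symbol (4.74) in the first block and of all probe sets (4.40) in the R848 arrays. This left 10139 named genes in the first block and 18898 probe sets in the R848 arrays. The deposited values carry no detection calls. Where a gene lay below the filter level (4.64 at rebuilt positions of the R848 arrays) in any array of the dimmer group, its difference has only a lower bound, written as "at least". The bound is the brighter group's mean minus the dimmer group's mean, with dimmer arrays raised to the filter level. No 2 arrays held identical values.

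The order of the values was checked before any test. The identifiers fitted 8 arrays by the levels of ribosomal protein and olfactory receptor genes, and 22 arrays held their values in another order. Sorted values differed by 0.0367, 0.0392 and 0.0307 on average between arrays of the same block and by 0.0997 to 0.2704 between blocks, so the 3 blocks were not treated as normalized together. Positions were rebuilt by aligning the mean profile of each block to that of the first block, within 800 positions, with a tolerance of 0.4 log2 and 5 neighbours on each side at the same shift. This placed 19843 of 28939 probe sets (68.6%) in the second block and 19208 (66.4%) in the third. Tested on simulated data, a re-sorted first block, the method placed 75.2% of probe sets, 97.9% of them at the right position. Differences between states were not used in the alignment. At rebuilt positions the TP minus TN difference of the second block correlated with that of the first at 0.586 across genes, against 0.076 at the preceding position and 0.0005 as deposited. Genes are not independent replicates, and no p-value was attached to these correlations.

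The design fixed before the data were examined was 1 fit of all 30 arrays with a mean per group. It could not be used, because the same position held different probe sets in different blocks. The contrasts, the filter, the gene lists, the thresholds and most alternatives were also fixed before the data were examined, and each block was fitted alone. R 4.3.3 and limma 3.58.1 were used, with a mean per group, moderated variances with an intensity trend, and Benjamini-Hochberg adjusted p under 0.05 for a call. "Rose" and "fell" are used of genes that passed this threshold. Differences are first state minus second on the log2 scale, SE is the moderated standard error, and levels are means with SD. Prepared tables and figures used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, Numba 0.67.0, SciPy 1.17.1 and Matplotlib 3.10.9. On data simulated from the means and spreads of first-block genes, with independent normal noise, limma recovered 65 of 100 genes changed by 1 on the log2 scale. It recovered 95 of 100 changed by 2, with 2 false calls. On data simulated alike from the R848 arrays (TP and DP) it recovered 86 and 100 of 100, with 10 false calls. Such data hold no correlated noise or outlying arrays, so these rates need not apply to the real arrays.

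Gene lists, 24 in number, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A preset value is more permissive, and none of the 43 list calls of the first block held with the estimated one. The estimated version also limits the test to the residual degrees of freedom, 4 in the first block and 9 in the R848 arrays. A call lost with it may thus reflect few arrays as well as correlation between genes. Limma's fry was also run: its p tests whether the genes of a list move on balance 1 way, its mixed p whether they change in either direction, and neither compares a list with other genes. Of the lists, those for B cells, plasma cells, T cells, granulocytes and epithelium stand for cells other than the sorted ones. Members can be shared: 5 of 25 macrophage genes on the array are in another list, as are 6 of 19 chemokine receptors and 5 of 24 uptake genes.

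Each comparison at deposited positions in the first and R848 blocks was rerun with other filters, scalings, variance models, thresholds, arrays left out and blocks. At rebuilt positions of the R848 arrays only the scaling, the neighbours needed and the TIM-4 pairs were varied. With an array of a state left out, the lone array is assumed to vary like the other states. Whether replicate numbers pair arrays was checked by the correlation of deviations from group means. It was 0.123, 0.107 and 0.219 for the 3 same-numbered pairs of TIM-4- and TIM-4+ arrays. The numbers may thus pair these arrays, as read from the data and not from the labels. The hint is weak, since R848 arrays with unlike numbers reached 0.169. No other 2 groups with 3 pairs had all correlations over 0.1, and the 2 steady-state blocks held 2 pairs per comparison. The labels call the replicates independent but give no sort days, so p-values do not cover variation between independent experiments that the pools do not hold. Comparisons of R848 with steady state and the overlap of responses in DP and TP were not tested, since block and treatment coincide. The R848 arrays were compared among themselves, as probe sets without names in the main text and at rebuilt positions in the closing observations. Raw image files were not analysed here.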

Results

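Peyer's patches are lymphoid organs of the small intestinal wall, and the phagocytes beneath their epithelium include monocyte-derived dendritic cells (LysoDC) and macrophages (LysoMac) that express lysozyme. Gene expression was measured on 30 oligonucleotide arrays hybridised with RNA of such cells sorted from mice, with the patches of 42 mice pooled for each replicate. At steady state, LysoDC were sorted into 4 states by the surface proteins embigin, JAM-A and CD24. TN cells lacked all of these, SP cells carried embigin, DP cells carried embigin and JAM-A, and TP cells carried embigin, JAM-A and CD24. The labels place TN cells mainly in the follicle and the other steady states mainly in the subepithelial dome. There were 4 arrays each of TN, SP and TP and 5 of DP. A further 13 arrays came from mice sampled 9 h after gavage with R848, a synthetic ligand of Toll-like receptor 7. They held 4 arrays of DP LysoDC, 3 of TP LysoDC, 3 of TIM-4- LysoMac and 3 of TIM-4+ LysoMac, TIM-4 being a phosphatidylserine receptor. The values were log2 expression levels, and array medians lay between 4.20 and 4.49. The number of arrays per group limits the precision of every value below, and since the labels give no sort days for the replicates, p-values measure only the spread between these pools.

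Gene names could be used directly for 8 of the 30 arrays, those of replicates 1 and 2 of the 4 steady states, called the first block here. In this block 205 ribosomal protein genes had a median log2 level of 12.2 and 1023 olfactory receptor genes one of 3.30. In the other 9 steady-state arrays (the second block) the same identifiers gave medians of 4.71 and 4.15, and in the 13 R848 arrays (the third block) 4.63 and 4.15. Arrays correlated at 0.9857 or more within a block and at 0.0521 or less between blocks. Named genes are therefore reported for the first block, with 2 arrays per state, and the R848 arrays are reported here as probe sets without names. Responses to R848 against steady state were not tested, because treated and untreated arrays lie in different blocks.

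The lysozyme genes and Tlr7, none of them part of the gate, were high in every steady state of the first block. Lyz1 and Lyz2, which encode lysozyme, had log2 levels of 13.15 ± 0.09 and 12.97 ± 0.08 (SD, n = 2) in TN and of 13.03 ± 0.05 and 12.86 ± 0.01 in TP. Tlr7, the receptor for R848, lay at 8.55 ± 0.09 in TN and 8.63 ± 0.01 in TP. The transcripts of embigin, JAM-A and CD24, which separate the states, followed the gates with 1 exception. Emb (probe set 10407327) rose between TN and SP, and F11r (probe set 10351623), which encodes JAM-A, rose between SP and DP. Cd24a (probe set 10362896) stood at 11.04 ± 0.15 in TP, 8.21 ± 0.40 in DP and 7.34 ± 0.03 in SP, but at 9.96 ± 0.47 in TN, which was sorted as lacking CD24. In the second block, at rebuilt positions, Cd24a was lower in TN than in SP and TP. By limma both differences were unlike those of the first block (adjusted p = 0.0118 and 0.0109). All LysoDC were sorted as CD4-, but Cd4 lay at 6.48 ± 0.52 in TN, 6.00 ± 0.37 in SP, 5.54 ± 0.06 in DP and 5.14 ± 0.03 in TP. Il6 and Il10 were too dim to be tested.

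SP and TN cells differ in the gate by embigin alone. Emb rose 10.1-fold in SP, from 6.16 ± 0.39 to 9.49 ± 0.04 (log2 level, SD, n = 2 per state), a log2 difference of 3.33 (SE 0.18, adjusted p = 9.57e-06). Hamp, which encodes the iron-regulating peptide hepcidin, rose at least 6.45-fold (log2 difference at least 2.69, adjusted p = 0.000198), and by 1.27 in the second block at rebuilt positions, a difference between blocks by limma (adjusted p = 0.016). The C-type lectin receptor genes Clec4a1 and Clec4a4 rose by 1.88 and 1.48 on the log2 scale, and Radx, a single-stranded DNA-binding protein gene, by at least 1.44. Itgam, the CD11b gene, rose by 0.88, Trem3, a myeloid receptor gene, by 1.07 and the chemokine gene Ccl5 by 1.60. Of genes known from macrophages and lysosomes, Ms4a7 fell by 0.80 and Atp6v0d2, a subunit of the vacuolar proton pump, fell by 2.06. Neither the macrophage nor the lysosome list was called by camera. In all, limma called 76 of 10139 genes, 15 higher and 61 lower in SP, and 62 of them differed at least 2-fold.

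Among the largest falls from TN to SP were genes of other cell types. Without the members of the 5 lists of other cells, limma called 59 genes, 47 of them lower in SP. That count does not leave out all genes of other cells, since Igha, S100a8 and S100a9 are in none of these lists. Jchain, the joining chain of IgA and IgM, was lower in SP by at least 4.46 on the log2 scale (adjusted p = 5.53e-05), and Igha and Mzb1 fell by at least 2.76 and 3.27. In the B cell list 7 of 14 tested genes fell, and 13 when adjusted over the list alone, among them Cd79a (-3.15) and, by at least 3.21, 2.54 and 0.08, Vpreb3, Ms4a1 and Cxcr5. The mean of this list was 6.95 ± 0.47 in TN and 5.26 ± 0.09 in SP (log2 level, SD, n = 2). In the plasma cell list 2 of 7 genes fell (2 adjusted over the list alone). Of 6 granulocyte genes 2 fell (3 adjusted over the list alone), Retnlg by at least 3.45 and Prg2, the eosinophil major basic protein gene, at least 5.68-fold. The plasmacytoid list lost 2 of 8 members (4 adjusted over the list alone), Blnk (at least 1.59 lower) and Ly6d (-2.71), which B lineage cells also express. The camera test placed these 4 lists below other genes, with adjusted p = 9.31e-23 for B cells, 0.000293 for plasma cells, 1.6e-05 for granulocytes and 0.00358 for the plasmacytoid list. All 4 calls were lost with an estimated correlation, where the adjusted p was 0.238, 0.25, 0.25 and 0.259. Outside these lists, the neutrophil genes S100a8 and S100a9, the eotaxin receptor gene Ccr3 and the enterocyte gene Fabp2 fell by at least 2.34, 2.03, 1.69 and 2.09. Plac8 (-3.20), H2-Oa (-1.77), H2-Ob (-1.79), Cd180 (-1.01) and Cd24a (-2.61) were lower in SP as well. Of the 14 B cell genes 6 lay at or above the median of named probe sets in every SP and DP array, as did 9 of the 9 T cell genes, 5 of the 7 plasma cell genes and 1 of the 6 granulocyte genes.

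The camera test called 5 further lists in this comparison. Of 9 T cell genes 1 rose in SP (3 adjusted over the list alone), Cd3d by at least 0.88, and the list lay above other genes (adjusted p = 1.21e-05). Of 19 genes of apoptotic cell uptake 1 fell (4 adjusted over the list alone), the scavenger receptor gene Cd36 by at least 1.07, and the list lay below other genes (adjusted p = 2.07e-05). With an estimated correlation these had adjusted p = 0.25 and 0.238. No member passed alone, by limma over all genes or over the list, in glycolysis (4 of 17 at unadjusted p under 0.05, median log2 difference 0.30), proliferation (5 of 29, median 0.29) and the interferon-stimulated list (1 of 24, median -0.22). Camera gave adjusted p = 0.00313, 4.1e-06 and 0.00397, and 0.401, 0.401 and 0.442 with an estimated correlation. The other 15 lists were not called, with adjusted p from 0.109 to 0.849. Among them the median, mean and direction of the test differed in sign for the inflammatory cytokine (median -0.14, tested upward), MHC class II (median 0.01, tested downward), monocyte (median 0.21, mean -0.15, tested upward) and toll-like receptor lists (mean -0.05, tested upward). In those 15 lists, the antimicrobial list held Hamp, S100a8 and S100a9 as called members (1 rose and 4 fell adjusted over the list alone), the monocyte list Itgam and Plac8 (5 rose and 2 fell) and the MHC class II list H2-Oa and H2-Ob (3 fell).

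Limits of the SP and TN comparison lie in the few arrays and in the block. Without SP replicate 1, SP replicate 2 or TN replicate 1 the count fell from 76 to 36, 39 or 44, and 13 of the 32 genes named passed with each array left out. In the second block, at rebuilt positions, 51 of 7256 genes were called, 37 higher and 14 lower in SP, and in both blocks together 85, 55 higher and 30 lower, so that most called genes were lower in SP in the first block alone, and by limma 25 of 7256 genes differed between the blocks. In the second block 12 of the 12 higher genes that could be placed but only 23 of the 40 lower ones differed in the same direction, and the B cell list had a median difference of 0.01 there. Of the named genes 13 of the 21 placed kept their direction, while Jchain, Mzb1, Vpreb3, Cxcr5, Plac8, H2-Oa, H2-Ob and Cd24a were higher in SP there.

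DP cells differ from SP cells in the gate by JAM-A. F11r rose 10.3-fold, from 6.22 ± 0.27 to 9.58 ± 0.20 (log2 level, SD, n = 2 per state; log2 difference 3.36, SE 0.20, adjusted p = 3.59e-05). Cd14, a co-receptor for lipopolysaccharide, rose 5.99-fold (log2 difference 2.58, SE 0.20, adjusted p = 0.000267). Plet1, a glycosylphosphatidylinositol-anchored surface protein gene, rose by 2.42 on the log2 scale, the lectin-like receptor gene Klrb1b by at least 2.90 and the orphan receptor gene Gpr141 by at least 2.34. The interferon-inducible gene Ifi205 rose by at least 2.25 and the acute-phase gene Saa3 by at least 1.89. Of cytokine and maturation genes, Il12b, the shared p40 chain of interleukins 12 and 23, rose by 1.52, and the chemokine gene Ccl22 by 1.81. The falls were smaller, with Itga9 at -1.08, Chst11 at -0.96, Cd81 at -0.51, the small nucleolar RNA Snord14e at -1.33 and another, Snord73a, at least 0.76 lower. The count by limma was 44 of 10139 genes, 39 higher and 5 lower in DP, and 36 differed at least 2-fold.

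Among the fixed lists, 2 of 19 genes of apoptotic cell uptake rose in DP (2 adjusted over the list alone), Cd36 by at least 1.77 and Cd300a by 1.20, but the list was not called (adjusted p = 0.53). In the maturation list 1 of 27 genes rose (5 rose and 1 fell adjusted over the list alone), and among 16 inflammatory cytokines 1 rose (3 adjusted over the list alone). These lists were not called either, with adjusted p = 0.464 and 0.238. The monocyte list gained 1 of 10 genes (2 adjusted over the list alone), Cd14, and lay above other genes (adjusted p = 0.0261, and 0.653 with an estimated correlation). Glycolysis gained 1 of 17 genes (5 adjusted over the list alone), Pfkp, the platelet form of phosphofructokinase, by 1.07, and was called higher (adjusted p = 0.00145, and 0.653 with an estimated correlation). Cholesterol synthesis was called higher with a median of 0.25, no gene passing over all genes by limma, 1 of 18 adjusted over the list alone and 7 at unadjusted p under 0.05 (adjusted p = 0.0261, and 0.653 with an estimated correlation). The lysosome list was called lower with a median of -0.02, no gene passing by limma and 2 of 31 at unadjusted p under 0.05. The macrophage list was called lower with a median of -0.10, although its 1 gene of 15 to pass, the phospholipid transfer protein gene Pltp, rose by 0.87 (2 rose and 1 fell adjusted over the list alone). These lists had adjusted p = 0.0261 and 0.0495, and 0.653 each with an estimated correlation. The other 19 lists had adjusted p from 0.052 to 0.743, and B cell, plasma cell and granulocyte list medians were -0.10, 0.10 and -0.05. Their median, mean and test differed in sign for 10 lists that were not called, among them the gate genes (median -0.07, mean 0.44, tested upward), the antimicrobial list (median 0.07, tested downward) and the uptake list (median -0.04, mean 0.09, tested downward). After quantile normalization the macrophage list had an adjusted p of 0.0881.

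The share of higher genes depended on scaling. Shifting all arrays to 1 median moved the median difference of all genes from 0.054 to -0.052 and the count to 27 genes, 18 higher and 9 lower, so that 66.7% and not 88.6% of called genes were higher (78.1% after quantile normalization). Without DP replicate 1 the count was 8, without DP replicate 2 or SP replicate 1 it was 14, and without SP replicate 2 it was 16. F11r, Klrb1b, Cd14, Plet1 and Gpr141, 5 of the 18 genes named, passed with each array left out, and in the second block 29 of 30 called genes that could be placed differed in the same direction. By limma 0 of 7256 genes differed between the blocks (255 at unadjusted p under 0.05).

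TP cells differ from DP cells in the gate by CD24. Cd24a rose 7.13-fold (log2 difference 2.83, SE 0.23, adjusted p = 0.000163, n = 2 per state). Several genes known from dendritic cells rose with it. Flt3, a growth factor receptor gene, rose by 1.76 and Itgae, the CD103 gene, by 2.85, but Itgae differed by 1.16 in the second block at rebuilt positions. Ccr7, which guides dendritic cells to T cell zones, rose by 1.06. Nr4a1, an orphan nuclear receptor gene, rose by at least 1.31. The 4 genes that fell were Aoah, a lipopolysaccharide-deacylating enzyme gene (-1.33), Rdh12, a retinol dehydrogenase gene (-1.24), Pclaf, a PCNA-binding factor of dividing cells (-1.17), and Cp, the ceruloplasmin gene (-0.81). In total 57 of 10139 genes were called by limma, 53 higher and 4 lower in TP, and 53 differed at least 2-fold.

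Among the largest rises from DP to TP were genes of other cell types. Without the members of the 5 lists of other cells, limma called 40 genes, 36 of them higher in TP. Igha, S100a8 and S100a9 are in none of these lists and stayed in the test, so this count does not leave out all genes of other cells. A kappa light chain variable gene was at least 39.0-fold higher in TP and Jchain at least 35.9-fold (log2 differences at least 5.29 and 5.17, adjusted p = 0.00166 and 3.97e-05). Igha rose by at least 3.48. In the B cell list 9 of 14 genes rose (11 adjusted over the list alone), including Vpreb3 (at least 4.06), Cd79a (3.44), Ms4a1 (at least 2.72), Fcer2a (at least 1.33) and Cxcr5 (at least 0.32). Its mean was 5.27 ± 0.18 in DP and 7.06 ± 0.10 in TP (log2 level, SD, n = 2). The plasma cell list gained 3 of 7 genes (4 adjusted over the list alone), Jchain, Mzb1 (at least 3.67) and Derl3 (1.01), and the granulocyte list 2 of 6 (3 adjusted over the list alone), Prg2 (at least 1.90) and Retnlg (at least 1.17). The epithelial list gained 1 of 6 genes (3 adjusted over the list alone), Fabp2 (2.05), and the plasmacytoid list 2 of 8 (5 adjusted over the list alone), Ly6d (3.37) and Blnk (at least 1.22). The camera test called the B cell list with adjusted p = 1.89e-33, the plasma cell list with 1.49e-07, granulocytes with 4.38e-07, the epithelial list with 0.00017 and the plasmacytoid list with 6.64e-11. With an estimated correlation the adjusted p was 0.069, 0.115, 0.146, 0.172 and 0.069. The T cell list did not move with them, with 0 of 9 genes passing by limma over all genes or over the list (1 at unadjusted p under 0.05), a median of -0.02 and adjusted p = 0.991.

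Of the other lists called between DP and TP, the antimicrobial and MHC class II lists gained genes of those same cell types. In the antimicrobial list 3 of 19 genes rose (3 rose and 1 fell adjusted over the list alone), the neutrophil genes S100a8 (at least 3.89), S100a9 (at least 3.65) and Pglyrp1 (2.65), while the list's median was -0.02 against an upward test (adjusted p = 0.0273). The MHC class II list gained 1 of 12 (3 adjusted over the list alone), H2-Oa (1.65), which B cells also express, with a median of -0.03 against an upward test (adjusted p = 0.0471). Those calls had adjusted p = 0.172 and 0.194 with an estimated correlation, and both medians turned positive (0.02 and 0.01) when arrays were shifted to 1 median. Among 14 chemokine receptors 2 rose (7 rose and 1 fell adjusted over the list alone), Cxcr5 and Ccr7, and among 16 conventional dendritic cell genes 2 rose (7 adjusted over the list alone), Flt3 and Itgae. Both lists were called higher (adjusted p = 1.21e-09 and 3e-10, and 0.115 and 0.157 with an estimated correlation). The monocyte list gained 2 of 10, Plac8 (3.49) and Nr4a1 (2 rose and 1 fell adjusted over the list alone), the toll-like receptor list 1 of 20, Cd180 (1.11; 1 adjusted over the list alone), and the maturation list 1 of 27, Ccr7 (1 rose and 1 fell adjusted over the list alone). These 3 lists were not called.

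A further 5 lists were called between DP and TP with no gene passing over all genes by limma. Proliferation was lower (median -0.38, 3 of 29 genes lower adjusted over the list alone, 11 at unadjusted p under 0.05, adjusted p = 6.42e-10), and so were glycolysis (median -0.24, 6 of 17 at unadjusted p under 0.05, adjusted p = 0.000152), lysosome (median -0.09, 5 of 31, adjusted p = 0.000995) and macrophage genes (median -0.10, 1 of 15 lower over the list alone, 5 unadjusted, adjusted p = 0.0071). The dissociation stress list was higher (median 0.16, 3 of 19 at unadjusted p under 0.05, adjusted p = 0.00128). With an estimated correlation the adjusted p was 0.196, 0.208, 0.217, 0.172 and 0.397. The lysosome call was lost after quantile normalization (adjusted p = 0.077). The other 10 lists had adjusted p from 0.058 to 0.991, and median, mean and test differed in sign for the uptake, gate, T cell and toll-like receptor lists among them.

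Leaving out DP replicate 1 or DP replicate 2 lowered the count of 57 to 16 or 27, and leaving out TP replicate 2 raised it to 89, while 12 of the 30 genes named passed with each array left out. In the second block 31 of 7256 genes were called, 20 higher and 11 lower in TP, and in both blocks together 78, 33 higher and 45 lower, so that the share of higher genes was not the same. By limma 16 of 7256 genes differed between the blocks, 15 of them higher in the first, among them S100a8, Pglyrp1, Vpreb3, Mzb1, Ms4a1, Cxcr5 and Jchain. In the second block 33 of 37 called genes that could be placed differed in the same direction, but 11 were called there in that direction, and the B cell list's median difference was 0.18 there. Of the 30 genes named, 19 could be placed there, with 18 in the same direction and 8 called.

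**Figure D1:**
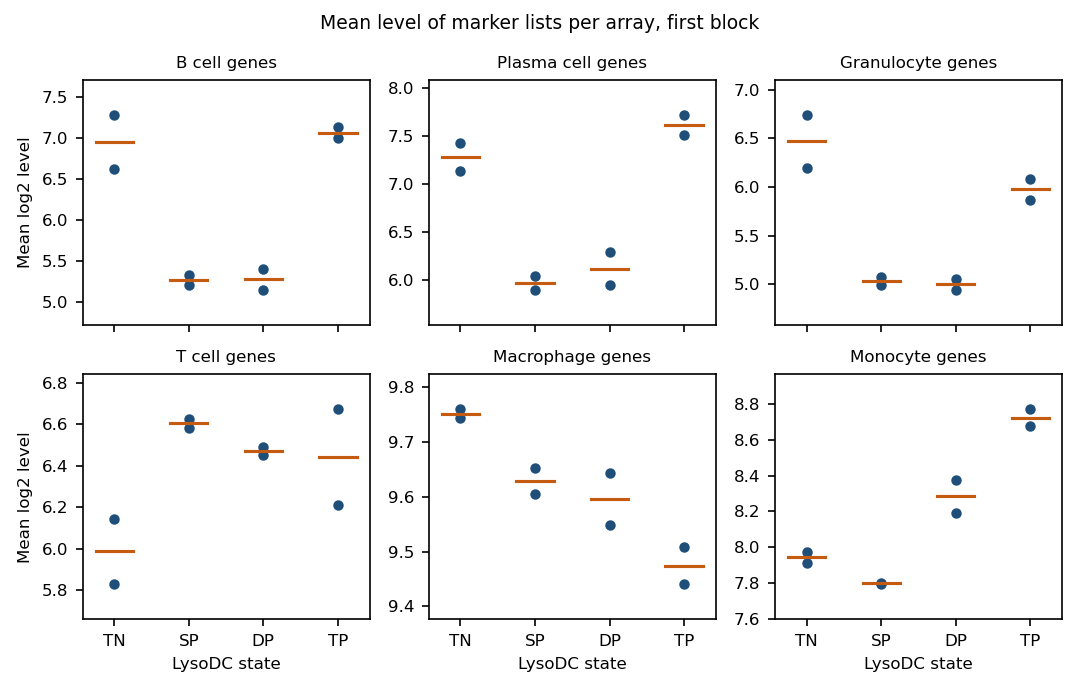
Mean log2 level of 6 marker lists (vertical axes, separate scales that do not start at 0) in the 8 first-block arrays by LysoDC state (horizontal axis), with a point per array and a line at the mean of the 2 arrays. The B cell list stood at 6.95 and 7.06 in TN and TP against 5.26 and 5.27 in SP and DP, while monocyte genes were highest in TP at 8.72 and macrophage genes highest in TN at 9.75.

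TP and TN cells are the ends of the marker series. Emb rose 15.4-fold in TP and F11r 7.52-fold (log2 differences 3.94 and 2.91, SE 0.18 and 0.20, adjusted p = 3.18e-06 and 3.41e-05, n = 2 per state). The receptor genes Klrb1b (at least 3.41), Gpr141 (at least 2.78) and Clec4a1 (2.99) rose, as did Ifitm1 (3.00), an interferon-induced membrane protein gene, Hamp (at least 2.86) and Radx (at least 2.50). Lower in TP were the integrin gene Itga9 (-2.31), the tetraspanin gene Tspan10 (-2.19) and Tlr12 (-2.14), a toll-like receptor gene. Igf1, insulin-like growth factor 1, Gdpd1, Egfl6 and the organic anion transporter gene Slco2b1 fell by at least 2.38, 2.17, 2.39 and 1.69. Limma called 240 of 10139 genes, 136 higher and 104 lower in TP, and 143 differed at least 2-fold.

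**Figure D2:**
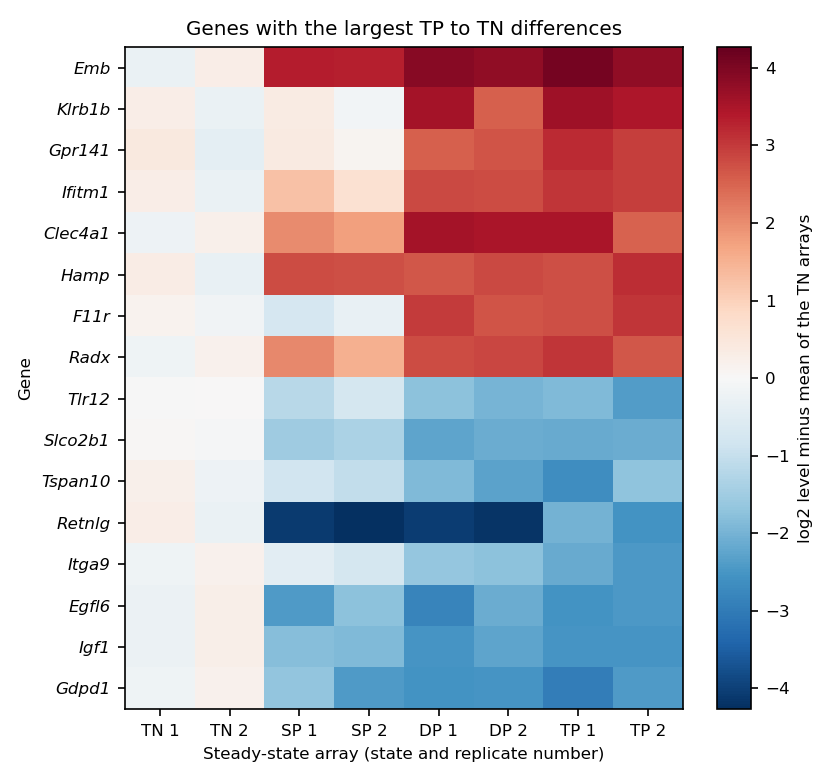
Log2 level minus the mean of the TN arrays (colour) for the 8 genes with the largest rise and the 8 with the largest fall between TN and TP (vertical axis) in the 8 first-block arrays (horizontal axis). Emb was 3.33 above TN in SP, F11r was 3.36 higher in DP than in SP, and Retnlg, a granulocyte gene, fell by at least 3.45 between TN and SP.

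Some monocyte and inflammatory cytokine genes rose from TN to TP, without a list call that held with an estimated correlation. Of 10 monocyte genes 3 rose (6 adjusted over the list alone), Cd14 by 2.83, S100a4 by 1.06 and Itgam by 0.87, and the list lay above other genes (adjusted p = 5.56e-07, and 0.112 with an estimated correlation). Of 16 inflammatory cytokines 5 rose (5 rose and 1 fell adjusted over the list alone), among them Il12b (1.85), Ccl5 (1.53), Tnf (1.35) and Il1b (0.80), with adjusted p = 0.00911, and 0.223 with an estimated correlation. Conventional dendritic cell genes gained 3 of 16 (8 adjusted over the list alone), Itgae (2.48), Kmo (1.54) and Flt3 (1.32), with adjusted p = 3.11e-05, and 0.36 with an estimated correlation. The maturation list gained 3 of 27 (4 rose and 1 fell adjusted over the list alone), Ccr7 (1.19), Stat4 (1.19) and Traf1 (0.71), but was not called (adjusted p = 0.235). Among 14 chemokine receptors Ccr7 and Ccr9 (1.18) rose and Ccr3 (at least 1.31 lower) and Cx3cr1 (-0.55) fell, with 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.0393, and 0.36 with an estimated correlation). Of 17 glycolysis genes Pfkp (at least 1.35) rose and Pfkfb3 (-0.45) fell, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.00632, and 0.36 with an estimated correlation).

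Some macrophage, lysosome and uptake genes fell in TP, also without a list call that held with an estimated correlation. Of 15 macrophage genes 4 fell (10 fell and 2 rose adjusted over the list alone), Ms4a7 by 1.12, Cx3cr1 by 0.55, the complement gene C1qb by 0.30 and the apolipoprotein gene Apoe by 0.24. Of 31 lysosome genes 3 fell (10 adjusted over the list alone), Atp6v0d2 by 1.67, the alpha-glucosidase gene Gaa by 0.56 and the cathepsin gene Ctsb by 0.50. Of 19 uptake genes 3 fell (10 fell and 1 rose adjusted over the list alone), Dock1 by 0.85, Axl by 0.78 and C1qb, while Cd36 rose by 1.65. Camera gave adjusted p = 1.68e-06, 4.05e-09 and 6.49e-05 for these 3 lists, and 0.129, 0.168 and 0.168 with an estimated correlation. Mertk, a receptor for apoptotic cells, differed by -0.81 and did not pass (adjusted p = 0.0514). Igf1, Atp6v0d2, Ms4a7, Cx3cr1, Apoe, Ctsb and Cd4, all lower in TP, were higher in LysoMac than in LysoDC after R848 at rebuilt positions. These genes therefore do not mark LysoDC states alone, and LysoMac RNA in the TN arrays was not tested for. Of 24 interferon-stimulated genes 1 fell (4 adjusted over the list alone), Irf7 by 0.92, with adjusted p = 0.000714, and 0.36 with an estimated correlation. The MHC class I list was called lower with a median of -0.18, no gene passing by limma and 2 of 15 at unadjusted p under 0.05 (adjusted p = 0.0265, and 0.36 with an estimated correlation).

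The B cell and granulocyte lists differed less in their medians between TP and TN (0.16 and -0.06) than between either and the middle states. The B cell list was not called (adjusted p = 0.395), with 1 of 14 genes higher (1 adjusted over the list alone), Fcer2a (at least 1.13). The plasma cell list was called higher with 1 of 7 genes (1 adjusted over the list alone), Derl3 (0.83), and the granulocyte list lower with 1 of 6 (1 adjusted over the list alone), Retnlg (-2.29). Their adjusted p was 0.0393 and 0.0487, and 0.36 and 0.361 with an estimated correlation, and the granulocyte list missed the threshold after shifting (0.0536) or quantile normalization (0.0648). Of 9 T cell genes Cd3d (at least 1.04) rose and Cd6 (-0.83) fell, with 2 higher and 1 lower adjusted over the list alone. In the plasmacytoid list Ccr9 and Cox6a2 (0.79) rose and Siglech (-1.35) fell (2 and 1 adjusted over the list alone), and in the epithelial list no gene of 6 passed by limma, with 2 higher adjusted over the list alone and 2 at unadjusted p under 0.05. These 3 lists were called higher with adjusted p = 0.0393 each, and 0.361, 0.36 and 0.36 with an estimated correlation, and the epithelial list had 0.116 after quantile normalization.

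The remaining 9 lists were not called between TP and TN, with adjusted p from 0.235 to 0.894. Of the antimicrobial list S100a8 (1.88), S100a9 (1.72) and Hamp rose and Cyba (-0.32) fell, with 6 higher and 3 lower of 19 adjusted over the list alone. In the stress list 1 of 19 rose, Ier3 (1.34; 1 adjusted over the list alone), and in the toll-like receptor list 2 of 20 fell, Tlr12 and Cd180 (-0.82; 2 rose and 3 fell adjusted over the list alone). Of 9 gate genes Emb, F11r and Cd24a (1.08) rose and Cd4 (-1.34) fell (3 and 2 adjusted over the list alone). At rebuilt positions of the second block, the difference of Cd24a was 4.78 (adjusted p = 1.45e-05) and that of F11r 4.45, and by limma both differed between the blocks (adjusted p = 0.0109 and 0.0238), as did 12 of 7256 genes in all. By limma 0 of 18 cholesterol synthesis, 0 of 29 proliferation and 0 of 12 MHC class II genes passed over all genes or over the list, with 3, 0 and 1 at unadjusted p under 0.05. Median, mean and test differed in sign for the MHC class II (mean 0.07, tested downward), toll-like receptor (median 0.04, tested downward) and gate gene lists (median -0.05, mean 0.63, tested upward).

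Without TP replicate 1 or TN replicate 2 the count of 240 fell to 148 or 128, and with only the arrays of these states in the fit it was 135. In the second block 165 of 168 called genes that could be placed differed in the same direction, and 141 were called there in that direction.

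After R848, probe sets without names were counted in the third block. Between TP and DP LysoDC, limma called 284 of 18898 probe sets, 97 higher and 187 lower in TP (n = 3 and 4), of which 74 differed at least 2-fold. The direction depended on scaling, since shifting arrays to 1 median gave 119 higher and 75 lower and quantile normalization 125 higher and 121 lower. The count was 71 with only these arrays in the fit, 153 or 80 without TP replicate 2 or 3, and 148, 171 or 181 without DP replicate 2, 3 or 4.

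TIM-4+ and TIM-4- LysoMac differed in 41 of 18898 probe sets after R848, 22 higher and 19 lower in TIM-4+ cells (n = 3 each), and 9 differed at least 2-fold. The count was 4 with only these arrays in the fit. It was 19 or 20 without TIM-4- replicate 1 or 2, and 21, 23 or 21 without TIM-4+ replicate 1, 2 or 3. LysoMac and LysoDC differed in 3771 of 18898 probe sets after R848, 1852 higher and 1919 lower in LysoMac (n = 6 and 7 arrays), and 343 differed at least 2-fold. The 6 LysoMac arrays may stand for only 3 pools, but were fitted as independent. The count lay between 3164 and 3952 with each array left out. After quantile normalization the larger share changed side in both comparisons, with 24 higher and 25 lower in TIM-4+ cells and 1934 higher and 1860 lower in LysoMac.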

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

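Tests chosen only after the result was seen in this part are those of failed arrays, of another material, of the order of values in steady-state arrays, of wrongly placed probe sets, of a lower share of LysoDC and of the first block as the source of the TP and DP difference.

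The identifiers fitted 8 of the 30 arrays. Failed arrays are argued against by the lowest correlation between arrays of a block, 0.9857. Values stored in another order may account for it: at rebuilt positions the TP minus TN difference of the second block correlated with that of the first at 0.586, and TP minus DP after R848 with the first block at 0.484, which also argues against another material (SP minus TN had the lowest correlation, 0.144). The gate genes Timd4, Cd4, H2-Aa, H2-Ab1 and H2-Eb1, 5 of the 5 that could be placed, differed in the direction of their gates, while Cd74 and Cd24a could not be placed. No biological explanation was tested.

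The SP minus TN difference was not the same in the 2 blocks of steady-state arrays, with 25 of 7256 genes differing by limma, 24 of them lower in the first block. B cell RNA in the TN arrays of the first block could account for part of it, since the median TN minus SP difference of the B cell list was 1.17 there and its SP minus TN median 0.01 in the second block. How much it leaves unexplained cannot be told from the lists of other cells: they hold 6 of the 25 genes but not the neutrophil gene S100a8, which also differed. Scd1 and Plet1 differed as well, and the labelled gate (CD11c high, SIRPa+) is meant to leave B cells out. Wrongly placed probe sets are argued against by a correlation of 0.684 between blocks for TP minus TN over the same genes. The design names no group that separates the 2 blocks, so no biological explanation was tested.

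In the first block Jchain, Cd79a, Retnlg and other genes of B cells, plasma cells and granulocytes were higher in TP than in DP. RNA of other cells that pass the CD24 gate may be the source, as the B cell list had a median of 0.75 after R848 as well, but the labelled gate (CD11c high, MHC class II high, SIRPa+, BST2+, CD4-) is meant to leave these cells out, and TN arrays, sorted as CD24-, held that list at 6.95 against 7.06 in TP. A lower share of LysoDC made up by cells of every type stays open: the T cell list had a median of -0.0198, but 9 of its 9 tested genes lay at or above the median of named probe sets in every SP and DP array. The arrays of the first block may account for part of the size, since 18 placed members of the B cell, plasma cell and granulocyte lists had a median of 1.01 in the first block and 0.21 in the second. CD24 expression by TP cells themselves, a biological difference named by the gate, stays open and untested.

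TP minus DP after R848 differed from that of the first block in 19 of 7421 genes at rebuilt positions by limma, all lower after R848. Among them were Mzb1, Vpreb3, Jchain, Itgae and Cd79a (-2.21), and 10 belong to the 5 lists of other cells. By camera, list medians differed by -1.44 for B cells, -0.72 for plasma cells, -0.47 for conventional dendritic cells, -0.34 for the plasmacytoid list, -0.21 for granulocytes and -0.21 for interferon-stimulated genes. With an estimated correlation the B cell (adjusted p = 0.0052), plasmacytoid (0.023) and granulocyte (0.044) calls held, and the plasma cell (0.0636), interferon (0.134) and dendritic cell (0.299) calls did not. Treatment and block coincide here, and an effect of R848 was not shown: over the 14 of these genes placed in the untreated second block, the median TP minus DP difference was 2.28 in the first block, 0.63 in the second and 0.42 after R848. Genes picked for a large first-block difference are expected to differ less elsewhere.

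The mean of the antimicrobial list in DP replicate 1 after R848 was 8.97, apart from the other 3 DP arrays by 0.960 of the group's range. Of 26 groups and measures tested this way 1 stood out, and chance gives about 1 in 20.

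Other splits of the R848 arrays were counted with limma. For TP and DP, 1 of 35 splits, the real one, gave 284 probe sets or more, and the highest other gave 1. That share of 2.86% is the smallest that 35 splits can give, so chance is made less likely but not excluded. In other splits the real difference adds to the spread, which lowers their counts. LysoMac and LysoDC gave 3771, reached by 1 of 100 splits, the smallest share possible, with 1860 in the highest other. At rebuilt positions the counts were 207 genes (1 of 35 splits, highest other 12) and 2060 genes (1 of 100, highest other 1). These were again the smallest shares possible. TIM-4+ and TIM-4- arrays allow 10 splits, too few for a share under 0.05, with 41 probe sets and 48 genes in the real split (1 of 10 each) and 1 in the highest other for both. If the replicate numbers pair these arrays, 4 splits part all 3 pairs, the real one included. The highest other was among the 6 that part 1 pair.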

How the results depend on the processing

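Tests chosen only after the results were seen are those with the second block, with both blocks, with a filter of 2 arrays, with scaling at rebuilt positions, with the TIM-4 pairs as a block and without the lists of other cells.

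The 76 genes of SP against TN became 43 with a stricter filter, 38 at adjusted p under 0.01 and 22 among unnamed probe sets of the second block, and 36 to 64 with each array left out (36 and 39 without SP replicate 1 and 2, 44 without TN replicate 1). The 44 genes of DP against SP became 22 without a filter, 27 with arrays shifted to 1 median, 17 without an intensity trend, 75 with array weights, 73 with only these states in the fit and 13 at adjusted p under 0.01. They became 76 in the second block at rebuilt positions, 192 in both blocks, 12 among unnamed probe sets of the second block and 8 to 16 with each array left out (8 and 14 without DP replicate 1 and 2, 14 and 16 without SP replicate 1 and 2). The 57 genes of TP against DP became 29 with a stricter filter, 32 at adjusted p under 0.01, 31 in the second block at rebuilt positions, 2 among its unnamed probe sets and 16 to 89 with each array left out (16 and 27 without DP replicate 1 and 2, 89 without TP replicate 2). The 240 genes of TP against TN became 135 with only these states in the fit, 143 at 2-fold or more, 125 at adjusted p under 0.01, 499 in the second block, 801 in both blocks, 457 among unnamed probe sets of the second block and 128 to 250 with each array left out (148 without TP replicate 1, 128 without TN replicate 2). Over all 18428 probe sets of the first block, the like of the unnamed counts, the 4 comparisons gave 27, 2, 25 and 92.

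After R848, the 284 probe sets of TP against DP became 181 without a filter, 176 with a stricter filter, 71 with only these groups, 74 at 2-fold or more, 42 at adjusted p under 0.01 and 80 to 356 with each array left out. Of these, 153 and 80 were without TP replicate 2 and 3, and 148, 171 and 181 without DP replicate 2, 3 and 4. The 41 of TIM-4+ against TIM-4- became 4 with only these groups, 9 at 2-fold or more, 18 at adjusted p under 0.01 and 19 to 31 with each array left out (19 and 20 without TIM-4- replicate 1 and 2, 21, 23 and 21 without TIM-4+ replicate 1, 2 and 3). The 3771 of LysoMac against LysoDC became 343 at 2-fold or more, 2306 at adjusted p under 0.01 and 3164 to 3952 with each array left out. With 12 neighbours on each side, the rebuilt counts of 207, 48 and 2060 genes became 131, 32 and 1273. Fewer genes were tested there, since 11856 and not 19208 probe sets were placed. With 5 neighbours the counts were 141, 62 and 2074 with arrays shifted to 1 median and 174, 57 and 2136 after quantile normalization.

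With the replicate number as a block the counts were 95, 66, 68 and 300 genes at steady state and 260, 35 and 4126 probe sets after R848. Residual correlations of same-numbered arrays had medians of 0.077, 0.069 and 0.055 in the 3 blocks, against -0.077, -0.063 and -0.031 for unlike numbers. With the block only for the TIM-4 arrays, which the numbers may pair, the counts after R848 were 248, 38 and 3829 probe sets, and 200, 66 and 2108 genes at rebuilt positions. By camera it gained the plasmacytoid list of TP against DP (adjusted p = 0.0334), the B cell list of TIM-4+ against TIM-4- (0.026) and the toll-like receptor list of LysoMac against LysoDC (0.0315), none of which held with an estimated correlation (0.225, 0.11 and 0.307), and 4 lists lost the call with an estimated correlation, as given in the observations. It changed no other call of a list or a named gene. Without the 5 lists of other cells the steady-state counts were 59, 46, 40 and 234.

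In the second block at rebuilt positions, the SP minus TN differences of Jchain (0.34), Mzb1 (0.026), Vpreb3 (0.050), Cxcr5 (0.013), Plac8 (0.55), H2-Oa (0.13), H2-Ob (0.29) and Cd24a (0.87) reversed, as did DP minus SP of Snord73a (0.14) and TP minus DP of Cd180 (-0.090). Other filters, variance models, the replicate block and fits of only the states compared leave first-block differences as they are. Signs could therefore reverse only under scaling, array weights, the mean of probe sets or a left-out array. Over 138 pairs of a named gene and a comparison, settings fixed before the data were examined gave 1693 values with the same call, 331 that lost it, 4 that gained it and 0 of the opposite sign, and those chosen later 125, 39, 2 and 10.

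Lists called by camera numbered 9, 5, 14 and 15 in the 4 steady-state comparisons, 0 in each of the 4 with an estimated correlation, and 5, 2, 9 and 6 by fry. Fry's mixed p called 16, 9, 16 and 18. Of the 43 calls, 38 held without a filter and 42 with the replicate block.

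Not run were all alternatives for R848 against steady state and for the overlap of responses, since these comparisons were not made, those for the difference between responses, the mean of probe sets for unnamed probe sets, and, at rebuilt positions, other filters, variance models, thresholds and left-out arrays.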

Other observations

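Tests chosen only after the order of values was seen are all those at rebuilt positions in this part.

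At rebuilt positions, TIM-4+ LysoMac after R848 differed from TIM-4- LysoMac (n = 3 each) by Timd4, the TIM-4 gene (probe set 10375472), at 10.27 ± 0.15 against 4.97 ± 0.26 (log2 difference 5.29, SE 0.13, adjusted p = 3.96e-14). Apoc1, an apolipoprotein gene, rose by 1.42, Gstm5 by at least 0.81, Tlr2 by 0.85 and the neutrophil gene S100a8 by 2.11. The MHC class II genes H2-Eb1 (-1.30), H2-Aa (-1.22) and H2-Ab1 (-1.14) fell, as did the cholesterol synthesis genes Idi1 (-0.76) and Sc5d (-0.66), Ifitm1 (-0.79), Il1b (-0.45) and Cd6 (-0.74). In all 48 of 7126 genes passed by limma, 21 higher and 27 lower. Cholesterol synthesis (2 of 12 genes fell, 7 adjusted over the list alone) and MHC class II (3 of 7 fell, 3 adjusted over the list alone) were called lower by camera, with adjusted p = 0.0261 for both with an estimated correlation, and 0.0605 for both with the TIM-4 pairs as a block. Interferon-stimulated genes were called higher with 0 of 20 passing by limma over all genes, 4 adjusted over the list alone and 6 at unadjusted p under 0.05 (adjusted p = 0.0432 with an estimated correlation, 0.0867 with the pairs as a block and 0.0619 with arrays shifted to 1 median).

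LysoMac differed from LysoDC after R848 (n = 6 and 7 arrays) by Cd4 (probe set 10547894), at 10.33 ± 0.25 against 5.05 ± 0.25 (log2 difference 5.29, SE 0.08, adjusted p = 1.27e-17). If the replicate numbers pair the TIM-4 arrays, the 6 LysoMac arrays stand for 3 pools but were fitted as independent. The p-values of this comparison may then be too small, and the pair block does not correct this. Higher in LysoMac were Clec1b (3.92), Igf1 (3.71), Atp6v0d2 (2.96), Mertk (1.51), Ms4a7 (1.00) and the chemokine gene Ccl3 (1.92). Lower were F11r (-3.31), H2-Eb1 (-2.52), S100a4 (-2.38), Ccr7 (-1.82) and Il1b (-1.25), while Clec4a4, Radx, Gpr141, Kmo, Stat4 and Il6 fell by at least 3.40, 3.06, 2.42, 1.66, 1.09 and 0.67. All 20 interferon-stimulated genes tested rose (20 adjusted over the list alone), Cmpk2 by at least 1.57 and Ifit3 by 1.12, with adjusted p = 2.47e-20, and 0.00193 with an estimated correlation. Of 11 uptake genes 8 rose (8 adjusted over the list alone; adjusted p = 0.039 with an estimated correlation, and 0.0885 with the pairs as a block), and of 18 maturation genes 11 fell and 3 rose (12 and 3 adjusted over the list alone; 0.13 with an estimated correlation). Of 12 cholesterol synthesis genes 10 fell (10 adjusted over the list alone; 0.0776 with an estimated correlation, 0.0255 when shifted to 1 median and 0.018 after quantile normalization). In all 2060 of 7126 genes passed by limma, 1086 higher and 974 lower, and 1012 and 1062 with arrays shifted to 1 median.

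TP LysoDC differed from DP LysoDC after R848 (n = 3 and 4) in 207 of 7126 genes by limma, 68 higher and 139 lower. The direction depended on scaling, with 91 higher and 50 lower when arrays were shifted to 1 median and 81 and 93 after quantile normalization. Ccr7 rose by 0.90, Tnfrsf9 by 1.06, Cd200 by 0.78, Cd83 by 0.61 and Tnf by 0.57, together with genes of other cells, S100a8, Jchain, Vpreb3 and Ms4a1 (at least 3.74, 2.93, 1.66 and 0.94). The cytokine genes Il15 (-0.55) and Il18 (-0.72) fell. Of 18 maturation genes 4 rose and 1 fell (camera adjusted p = 0.00426, and 0.291 with an estimated correlation). Bub1 (-1.17), Top2a (-1.12), Pclaf (-0.98), Kif11 (at least 0.75 lower) and Ccna2 (-0.81), genes of dividing cells, fell, as did Oas2 (-0.66) and Mx1 (-0.62). Of 26 proliferation genes 13 fell (22 adjusted over the list alone; adjusted p = 4.3e-16, and 0.074 with an estimated correlation, or 0.0316 with either scaling), and of 20 interferon-stimulated genes 3 fell (13 adjusted over the list alone; 6.37e-07, and 0.0507, or 0.00428 after quantile normalization and 0.0883 when shifted to 1 median). Of 8 B cell genes 6 rose (6 adjusted over the list alone), and that call held (adjusted p = 0.00255 with an estimated correlation). About 2 in 100 placed probe sets were misplaced in the simulated re-sorting of the first block. That was an easier case, with 75.2% of probe sets placed against 66.4% in the R848 arrays, so the error here may be larger. A single name here is less secure than one from the first block.

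Pclaf fell from DP to TP in the first block (-1.17), in the second block (-1.05) and after R848 (-0.98). In the second block 4 of 20 proliferation genes fell between DP and TP (median -0.50; adjusted p = 0.0513 with an estimated correlation).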
